A study of Bos taurus with 6 samples.

How the data were processed

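The series holds 6 RNA-seq libraries of bovine late morulae, 2 for each of the nonspecific, NOTCH1 and RBPJ small interfering RNA groups, with 15 embryos per library. Per the labels' protocols, RNA was extracted with a kit for small samples after equal amounts of GFP and RFP messenger RNA had been added as a spike-in, polyadenylated RNA was selected with oligo(dT) beads, and fragmented libraries were amplified by PCR. Per the submitters' processing notes, Salmon 0.14.1, DESeq2 and the genome build ARS-UCD1.2 were used, with no role or order given. The annotation, the filters and the way transcripts were summed to genes are not given in the sources used here. Nothing in the labels says whether replicates came from separate oocyte collections, so p-values measure the spread between these libraries, which may be technical.

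The deposited table holds one signal value per gene and library: read counts divided by the authors' scaling factors, as judged from the values. Most low values are whole multiples of 1 step per library, with 81.6% to 83.9% of them within 0.1 of a multiple. This was too few for whole reads to be recovered, so no count-based test was run. Dividing the totals by the steps gives an approximate depth of 9620000 to 13700000 reads, with replicate 1 of the RBPJ knockdown the deepest. The 2551 of 17922 rows without a gene name, which held 6.20% to 7.22% of a library's total, were left out. Of the 15371 named rows, 57 repeated a symbol, and the row with the higher mean kept it. No rows of GFP or RFP were used here, so the total RNA per embryo pool and a scaling by spike-in were not analysed. Transcripts of near-identical gene copies, such as histone genes and ribosomal protein genes with processed pseudogenes, can share reads in a way that the deposited values do not show, and so can overlapping and antisense genes. Gene symbols are those of the table, and no coordinates are given because the reference at hand is of another build.

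Values were analysed as log2(value + 1) without further scaling, so fold changes understate those of low genes. The 12101 named genes with a mean of at least 10 over the 6 libraries were tested with limma 3.58.1 in R 4.3.3. A group-means model over all 6 libraries left 3 residual degrees of freedom, and variances were moderated with a trend on expression level. The Benjamini-Hochberg adjusted p had to lie below 0.05. Calls refer to this model, without a replicate block, unless a block is named. The 27 gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. List members were also adjusted over the list alone. The tests, lists and alternatives were fixed before the data were examined, for both possible kinds of value. The rule for named genes was fixed too: the targeted genes; genes past the threshold with both libraries of one group on the same side of both of the other; where fewer than 10 passed, the 10 genes with the smallest p; and per list up to 4 members past the threshold or, where fewer than 2 passed, the 3 with the smallest p, given as values. Since the comparisons against the control share its libraries, 100 pairs of unchanged groups, simulated with the same spread in every group, gave an agreement without effects.

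The fit was tested on simulated counts for the 12101 genes of the NOTCH1 knockdown comparison, drawn at their means and depths, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 84.0% of the former and 88.0% of the latter, with 11 false calls among 183. Where replicates also shared an effect, it recovered 59.0% and 96.0% with 0 false calls. The simulated spread was smoothed over expression level, so these shares need not hold for the real values. There CYP1A1 did not pass in the NOTCH1 knockdown at a log2 fold change of -1.95. A shifted list was recovered and none of 26 unshifted lists was called. Genes were drawn independently and these lists were random, so this could not show false calls from members that vary together. In the real lists the estimated correlation between members reached 0.631, for cholesterol and fatty acid synthesis genes. Alternatives were pseudocounts of 0.1 and 10, no filter, a minimum mean of 100, median-of-ratios scaling, quantile normalization, only the groups compared, variance moderation without the trend or with a robust option, other thresholds, a replicate block and the omission of each library. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.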

Results

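Polyadenylated RNA was sequenced from pools of bovine embryos at the late morula stage, 6 days after in vitro fertilization. The embryos had been injected with a small interfering RNA against NOTCH1, with one against RBPJ, or with a nonspecific one that served as the control. NOTCH1 encodes a receptor of the NOTCH signalling pathway, and RBPJ encodes the DNA-binding protein through which activated NOTCH receptors regulate transcription. Each of the 3 groups had 2 libraries, and each library was made from 15 embryos. The comparisons ask which transcripts depend on either component at the stage before the blastocyst forms. The deposited values are read counts scaled by the authors. Their totals ran from 10365700 to 10815600 per library, and 12101 named genes had a mean of at least 10.

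RBPJ fell in the embryos injected with its own small interfering RNA. The scaled count was 419 ± 39.6 (SD, n = 2) in the control and 108 ± 18.5 (SD, n = 2) in the RBPJ knockdown, a fold change of 0.257. The log2 fold change was -1.96 with a standard error of 0.18 (limma, adjusted p = 0.00149), and both knockdown libraries, at 121 and 94.5, lay below both control libraries, at 447 and 391. In the NOTCH1 knockdown RBPJ stood at 361 and 400 (log2 fold change -0.14, limma adjusted p = 0.911). NOTCH1 was a low transcript that differed between the control libraries, at 69.6 and 140. It stood at 48.0 and 49.5 in the NOTCH1 knockdown, below both controls, with a log2 fold change of -1.003 and a standard error of 0.42 that did not pass (limma, adjusted p = 0.637). In the RBPJ knockdown the libraries held 50.0 and 125, so that replicate 1 of that group was as low in NOTCH1 as the NOTCH1 knockdown libraries. The RBPJ call was lost when the variance was moderated without its trend on expression level (limma, adjusted p = 0.332).

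**Figure D1:**
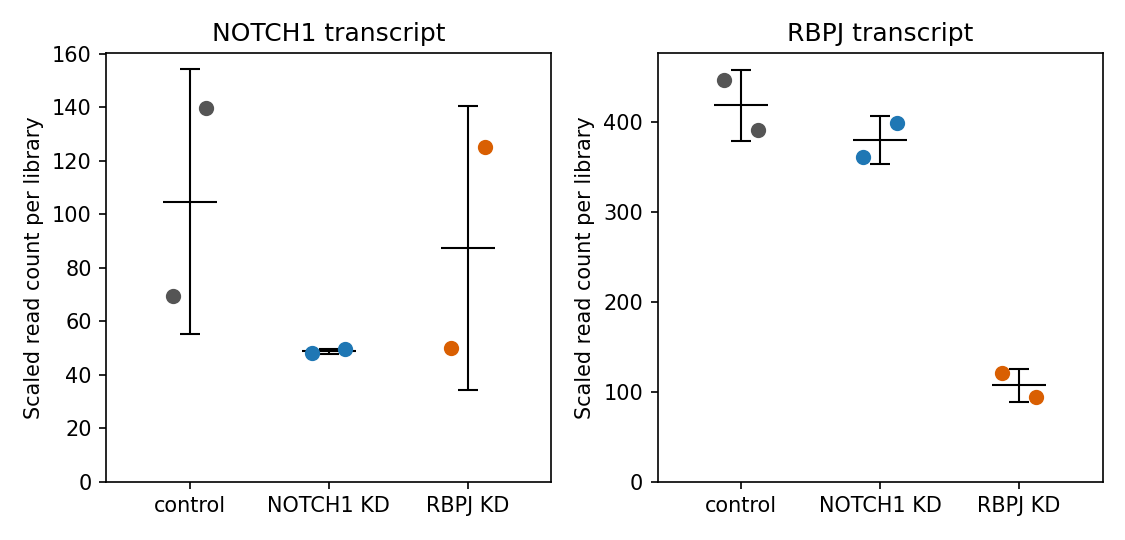
Scaled read counts of NOTCH1 (left) and RBPJ (right) in each group; dots are libraries, horizontal bars group means and error bars SD (n = 2). RBPJ lies at 121 and 94.5 in the RBPJ knockdown, below the control libraries at 447 and 391, while NOTCH1 lies at 48.0 and 49.5 in the NOTCH1 knockdown and spreads from 69.6 to 140 in the control.

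In NOTCH1 knockdown embryos, transcripts that the oocyte stores for the early embryo were lower as a list, although libraries of both groups overlapped. Markers of the hypoblast, the layer that lines the yolk sac, rose as a group. Junction, polarity and fluid transport genes, trophectoderm markers, inner cell mass and pluripotency markers, glycolysis genes and mitochondrially encoded genes also rose as lists. Lists of stress response, ribosomal protein, ribosome biogenesis and mitotic genes fell. These 11 of the 27 lists passed camera with its preset correlation of 0.01, 6 upward and 5 downward. None of the 11 passed with an estimated correlation, where the smallest camera adjusted p was 0.332. The estimated correlation of stress, pluripotency and glycolysis genes, at 0.00314, -0.00327 and -0.0118, lay below the preset 0.01. Their loss therefore does not come from a higher correlation between members. In the other lists that passed the estimate was higher than the preset value, up to 0.383 for mitotic genes. No single gene passed without a replicate block.

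Of 29 tested oocyte and maternal transcripts, 24 were lower by sign in the NOTCH1 knockdown, with a median log2 fold change of -0.71 (camera, adjusted p = 3.94e-06; adjusted p = 0.486 with an estimated correlation). H1FOO, the oocyte linker histone, had values of 40.9 and 51.7 in the control and 1.04 and 17.1 in the knockdown. BTG4, a factor in the clearance of maternal messenger RNA, had 107 and 113 in the control and 11.2 and 63.7 in the knockdown. CNOT6L, a deadenylase subunit, had a log2 fold change of -0.49. None of these members passed, and none passed when adjusted over the list alone. Relative to each gene's mean over the libraries, the list's median was 0.08 and 0.56 in the control and -0.57 and 0.14 in the knockdown. Replicate 2 of the knockdown thus lay above replicate 1 of the control. The drop was carried by low transcripts: among genes with a mean of at least 100 the list's median was -0.08 (camera, adjusted p = 0.239).

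Of 19 tested hypoblast markers, 15 were higher by sign in the NOTCH1 knockdown, with a median log2 fold change of 0.18 (camera, adjusted p = 0.000143; adjusted p = 0.332 with an estimated correlation). None passed over all genes, and 6 passed upward when adjusted over the list alone. LAMA1, a laminin chain of basement membranes, had 353 and 214 in the control and 792 and 654 in the knockdown, a log2 fold change of 1.38 with a standard error of 0.28. NID2, another basement membrane protein, had a log2 fold change of 0.40, and APOE, a lipid carrier, one of 1.04. Of 37 junction, polarity and fluid transport genes, 32 were higher by sign (median 0.14; camera, adjusted p = 0.000134; adjusted p = 0.486 with an estimated correlation), and 2 passed when adjusted over the list alone. DSP and JUP, both desmosome components, had log2 fold changes of 0.46 and 0.56.

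Trophectoderm markers had a median log2 fold change of 0.19 over 26 tested genes in the NOTCH1 knockdown (camera, adjusted p = 0.0218; adjusted p = 0.723 with an estimated correlation). The median ran from 0.09 without replicate 1 of the NOTCH1 knockdown to 0.45 without its replicate 2. None passed when adjusted over the list alone, and members went both ways, with 19 higher and 7 lower by sign. GATA3, a trophectoderm transcription factor, had 577 and 515 in the control and 1018 and 856 in the knockdown. TFAP2A, another one but a low transcript, had 31.1 and 20.0 in the control and 6.37 and 8.63 in the knockdown, a log2 fold change of -1.62. Inner cell mass and pluripotency markers had a median of 0.14 over 23 genes (camera, adjusted p = 0.0125; adjusted p = 0.332 with an estimated correlation), with 1 passing when adjusted over the list alone. LIN28A and DNMT3B had log2 fold changes of 0.60 and 0.81, and POU5F1 one of 0.20. The median of the inner cell mass and pluripotency list ran from 0.08 to 0.23 over omitted libraries. Glycolysis and glucose transport genes had a median of 0.17 over 25 genes (camera, adjusted p = 0.00670; adjusted p = 0.332 with an estimated correlation), with LDHA at 0.62 and PFKFB3, a regulator of glycolysis, at -0.91. The 13 mitochondrially encoded genes had a median of 0.10 (camera, adjusted p = 0.0294; adjusted p = 0.734 with an estimated correlation), which became 0.00 after quantile normalization (camera, adjusted p = 0.725).

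Integrated and unfolded protein stress genes were lower by sign in 28 of 33 cases in the NOTCH1 knockdown (median -0.17; camera, adjusted p = 0.00019; adjusted p = 0.332 with an estimated correlation), and 1 passed downward when adjusted over the list alone. PHGDH, the first enzyme of serine synthesis, had a log2 fold change of -0.82, and HSPA5, the main chaperone of the endoplasmic reticulum, one of -0.34. Ribosomal protein genes shifted slightly, with a median of -0.07 over 75 genes (camera, adjusted p = 0.000837; adjusted p = 0.738 with an estimated correlation); RPL39 had a log2 fold change of -0.43. Without replicate 1 of the control the ribosomal protein median was -0.01 (camera, adjusted p = 0.377), and the lowest over omitted libraries was -0.13. Ribosome biogenesis genes had a median of -0.06 over 44 genes (camera, adjusted p = 0.00953; adjusted p = 0.618 with an estimated correlation), and G2 and mitosis genes one of -0.08 over 39 (camera, adjusted p = 0.0148; adjusted p = 0.834 with an estimated correlation).

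NOTCH pathway components had a median log2 fold change of 0.05 over 40 genes in the NOTCH1 knockdown (camera, adjusted p = 0.566), and NOTCH target genes one of -0.00 over 14 genes (camera, adjusted p = 0.902). When adjusted over the list alone, 2 targets passed, GATA3 upward (log2 fold change 0.78) and MYC downward (-0.94). MYC had 93.0 and 115 in the control and 61.2 and 46.5 in the knockdown, and HEYL, which did not pass, had 87.9 and 52.3 in the control and 106 and 154 in the knockdown. HEY1 and HEY2, which did not pass either, had log2 fold changes of -0.41 and -0.77. HES1, which did not pass, had 275 and 345 in the control and 387 and 357 in the knockdown. HEY1, HEY2 and HES1 were not among the targets that the naming rule gave here. Of the 14 targets, 7 were higher and 7 lower by sign. Of lists that mark other cell types, cumulus, granulosa and fibroblast markers had a camera adjusted p of 0.614 and blood and immune cell markers one of 0.362. All lists that did not pass had camera adjusted p values of 0.164 to 0.993.

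Among single genes in the NOTCH1 knockdown, B3GNT6, a glycosyltransferase of mucin-type glycans, had the smallest p. It had 117 and 106 in the control and 527 and 272 in the knockdown, a log2 fold change of 1.76 with a standard error of 0.29 (limma, adjusted p = 0.348). KIAA1671, LRRN2, SHROOM1 and MYADM, at log2 fold changes of 1.29, 0.96, 0.79 and 0.53, and CYP1A1, MT2A, TCAM1, C21H15orf40 and CENPI, at -1.95, -0.95, -1.20, -0.94 and -0.62, completed the 10 genes with the smallest p. CYP1A1, a cytochrome induced by the aryl hydrocarbon receptor, had 470 and 231 in the control and 81.7 and 87.2 in the knockdown. limma called 0 genes, with 881 at an unadjusted p below 0.05, of which 552 were higher, where chance gives 605. With the replicate number as a block, treated below, it called 135. Of the 11 list calls, those of hypoblast, stress and maternal transcripts held without each library in turn, although the hypoblast median ran from 0.14 to 0.36 and the maternal one from -1.04 to -0.27, nearest 0 without replicate 1 of the NOTCH1 knockdown; that omission ended 6 list calls, including junction genes (adjusted p = 0.0601) and trophectoderm markers (adjusted p = 0.475). Without replicate 1 of the control 4 calls were lost and the mitotic genes' median turned to 0.04, and omitting replicate 2 of the control or of the NOTCH1 knockdown ended 2 calls each, among them ribosome biogenesis and ribosomal protein genes.

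**Figure D2:**
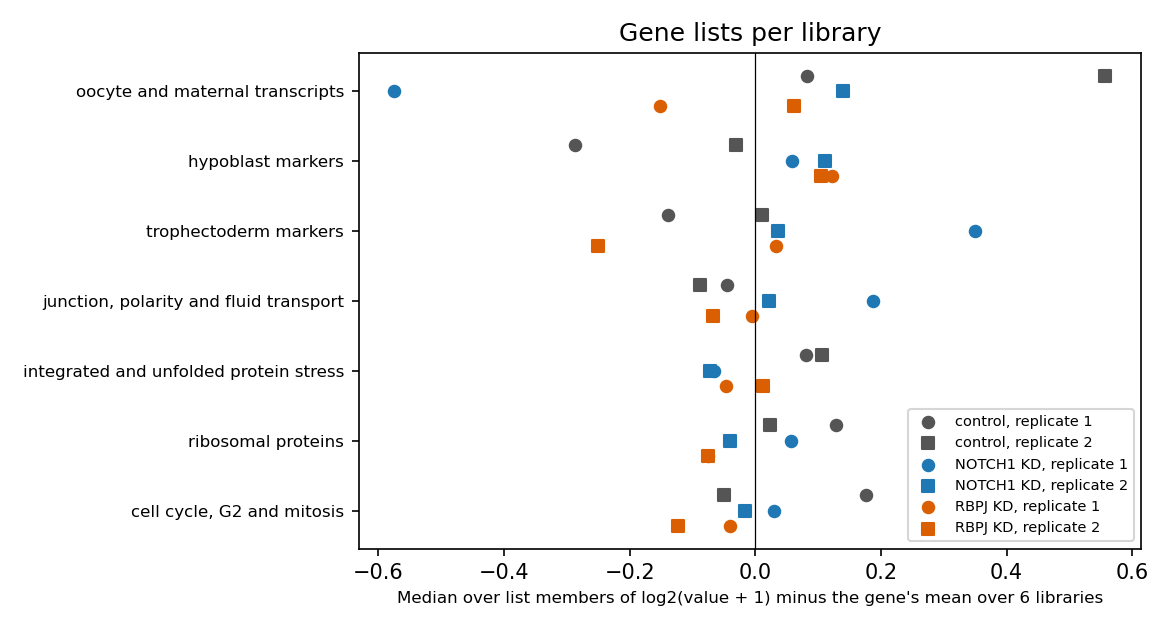
Median over the tested members of 7 gene lists of log2(value + 1) minus the gene's mean over the 6 libraries, per library; colours mark groups, circles replicate 1 and squares replicate 2. Maternal transcripts lie at 0.08 and 0.56 in the control, -0.57 and 0.14 in the NOTCH1 knockdown and -0.15 and 0.06 in the RBPJ knockdown, and hypoblast markers lie at -0.29 and -0.03 in the control and between 0.06 and 0.12 in all 4 knockdown libraries.

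In RBPJ knockdown embryos, hypoblast markers rose as a group and oocyte and maternal transcripts fell as a group, as in the NOTCH1 knockdown. Ribosomal protein, ribosome biogenesis, mitotic, DNA replication, oxidative phosphorylation, cholesterol and fatty acid synthesis, and stress response genes fell as lists. These 9 of the 27 lists passed camera with the preset correlation, 1 upward and 8 downward. None of the 9 passed with an estimated correlation, where the smallest camera adjusted p was 0.505. Stress genes lost their call at an estimated correlation of 0.00314, below the preset 0.01, so a higher correlation between members does not account for it. In the other lists that passed the estimate was higher than the preset value, up to 0.631 for cholesterol and fatty acid synthesis genes. RBPJ itself was the single gene that passed without a replicate block.

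Of 75 tested ribosomal protein genes, 73 were lower by sign in the RBPJ knockdown, by a small and even amount: the median log2 fold change was -0.15 (camera, adjusted p = 2.63e-18; adjusted p = 0.505 with an estimated correlation). RPL39 had a log2 fold change of -0.30 and RPS24 one of -0.30. Ribosome biogenesis genes were lower by sign in 38 of 44 cases (median -0.10; camera, adjusted p = 3.96e-05; adjusted p = 0.505 with an estimated correlation), with NOP56, a nucleolar protein of small nucleolar ribonucleoproteins, at -0.26. G2 and mitosis genes were lower in 36 of 39 cases (median -0.16; camera, adjusted p = 1.01e-08; adjusted p = 0.505 with an estimated correlation). PTTG1 (securin) had 1068 and 905 in the control and 755 and 714 in the knockdown, and CDK1 had a log2 fold change of -0.34. DNA replication genes had a median of -0.06 over 44 genes (camera, adjusted p = 0.0300; adjusted p = 0.625 with an estimated correlation), with CDC6, a factor that loads the replicative helicase, at -0.41. None of the members of these lists passed when adjusted over the list alone. Over omitted libraries the DNA replication median ran from -0.13 to -0.01.

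Hypoblast markers were higher by sign in 15 of 19 cases in the RBPJ knockdown, with a median log2 fold change of 0.29 (camera, adjusted p = 1.84e-05; adjusted p = 0.505 with an estimated correlation), and 1 passed when adjusted over the list alone. NID2 had 2748 and 2309 in the control and 3318 and 3463 in the knockdown, and GATA6 and SOX17, transcription factors of the hypoblast lineage, had log2 fold changes of 0.34 and 0.73. Maternal transcripts were lower by sign in 24 of 29 cases (median -0.46; camera, adjusted p = 0.000356; adjusted p = 0.505 with an estimated correlation). ZP3, a zona pellucida glycoprotein, had 62.4 and 79.5 in the control and 43.1 and 31.8 in the knockdown, and KHDC3L, a component of the oocyte's subcortical maternal complex, had a log2 fold change of -1.04. Among genes with a mean of at least 100 the maternal median was -0.08 (camera, adjusted p = 0.609).

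Nuclear-encoded oxidative phosphorylation genes were lower by sign in 56 of 68 cases in the RBPJ knockdown (median -0.07; camera, adjusted p = 0.000346; adjusted p = 0.599 with an estimated correlation). Cholesterol and fatty acid synthesis genes had a median of -0.15 over 29 genes (camera, adjusted p = 0.00706, and adjusted p = 0.746 with an estimated correlation). This median ran from -0.22 to -0.04 over omitted libraries. HMGCS1, an early enzyme of cholesterol synthesis, had a log2 fold change of -0.52 and FADS2, a fatty acid desaturase, one of -0.39. Stress response genes had a median of -0.14 over 33 genes (camera, adjusted p = 0.0122; adjusted p = 0.505 with an estimated correlation), with PHGDH at -0.59 and HSPA5 at -0.30. NOTCH target genes had a median of 0.20 over 14 genes (camera, adjusted p = 0.0998), with 11 higher and 3 lower by sign. Among these targets HEYL had a log2 fold change of 0.69 and HEY2 one of -0.55. NOTCH pathway components had a median of 0.05 over 40 genes (camera, adjusted p = 0.579). Trophectoderm markers had a median of -0.06 (camera, adjusted p = 0.394), with TKDP1, a trophoblast Kunitz domain protein, at 175 in replicate 1 of the control and between 15.3 and 21.4 in all other libraries. Cumulus, granulosa and fibroblast markers had a camera adjusted p of 0.560 and blood and immune cell markers one of 0.579, within the range of 0.0998 to 0.922 over all lists that did not pass.

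After RBPJ, the genes with the smallest p in the RBPJ knockdown were B3GNT6, TANC2, A2M, SDS, CYP4F2, LGMN, MYH14, PDZD4 and CNGB3. B3GNT6 had 427 and 264 in the knockdown, a log2 fold change of 1.58 with a standard error of 0.29 (limma, adjusted p = 0.544). SDS, serine dehydratase, had 358 and 424 in the control and 1108 and 806 in the knockdown, and CYP4F2, a fatty acid hydroxylase, had a log2 fold change of -1.68. limma called 1 gene, with 524 at an unadjusted p below 0.05 where chance gives 605. With the replicate number as a block it called 12. The calls for ribosomal protein, hypoblast and oxidative phosphorylation genes held without each library in turn, with a hypoblast median of 0.15 to 0.31, while maternal transcripts lost theirs without replicate 2 of the control (median -0.18, adjusted p = 0.112) or replicate 1 of the RBPJ knockdown (median -0.25, adjusted p = 0.0826). Omitting replicate 1 of the control ended 3 of the 9 calls, including mitotic genes (adjusted p = 0.191), replicate 1 of the RBPJ knockdown 4, replicate 2 of that group 2, and replicate 2 of the control 2.

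Compared directly, the knockdowns differed in RBPJ, which was 3.54 times as high in the NOTCH1 knockdown, with a log2 fold change of 1.82 (standard error 0.18; limma, adjusted p = 0.00332). Trophectoderm markers were higher in the NOTCH1 knockdown than in the RBPJ knockdown as a list, as were junction, ribosomal protein, oxidative phosphorylation, DNA replication and mitotic genes. These 6 lists passed camera upward and none passed downward. With an estimated correlation none of the 6 passed, and the smallest camera adjusted p was 0.550. Trophectoderm markers were higher by sign in 21 of 26 cases (median 0.27, camera adjusted p = 0.000268, and adjusted p = 0.550 with an estimated correlation). This median ran from 0.09 to 0.37 over omitted libraries, and 3 members passed when adjusted over the list alone. GATA3 had a log2 fold change of 0.80, with 1018 and 856 in the NOTCH1 knockdown and 737 and 391 in the RBPJ knockdown; it was chosen after its values were seen.

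Junction, polarity and fluid transport genes were higher by sign in 31 of 37 cases in the NOTCH1 than in the RBPJ knockdown (median 0.11; camera, adjusted p = 6.51e-05; adjusted p = 0.550 with an estimated correlation). Ribosomal protein genes were higher in 69 of 75 cases (median 0.08; camera, adjusted p = 4.23e-06; adjusted p = 0.588 with an estimated correlation) and oxidative phosphorylation genes in 58 of 68 (median 0.08; camera, adjusted p = 0.000266; adjusted p = 0.588 with an estimated correlation). DNA replication genes had a median of 0.10 (camera, adjusted p = 0.000577; adjusted p = 0.550 with an estimated correlation) and mitotic genes one of 0.09 (camera, adjusted p = 0.00603; adjusted p = 0.730 with an estimated correlation). Hypoblast markers had a median of 0.01 (camera, adjusted p = 0.856), maternal transcripts one of -0.21 (camera, adjusted p = 0.0753) and NOTCH target genes one of -0.26 (camera, adjusted p = 0.0733). limma called 1 gene, with 441 at an unadjusted p below 0.05 where chance gives 605. With the replicate number as a block it called 15. All 6 list calls were lost without replicate 1 of the NOTCH1 knockdown, and omitting replicate 2 of the RBPJ knockdown left 3 lists. The RBPJ call was lost without replicate 1 or replicate 2 of the NOTCH1 knockdown, with log2 fold changes still at 1.89 and 1.75. Quantile normalization ended the calls of ribosomal protein (camera, adjusted p = 0.139) and mitotic genes (camera, adjusted p = 0.124).

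Both knockdown effects had a Pearson correlation of 0.580 across 12101 genes, which are not independent replicates. Because they share their control libraries, unchanged groups simulated with the same spread per gene in every group already gave 0.500. The control libraries were the least alike pair within a group, correlating at 0.980 against 0.985 (NOTCH1 knockdown) and 0.984 (RBPJ knockdown). A larger spread in the shared controls would raise the simulated agreement, so the differences from simulation given here cannot be assigned to shared effects. The covariance was 0.0584 against a simulated 0.0392, a difference of 0.0192. The share of genes with the same sign was 70.8% against a simulated 66.7%. At an unadjusted p below 0.05, 150 genes were higher in both knockdowns, where simulation gave 57.3 and independent lists 15.5, and 45 were lower in both, where simulation gave 56.2 and independent lists 5. The higher lists held 552 (NOTCH1 knockdown) and 340 (RBPJ knockdown) genes and the lower ones 329 and 184. Simulated lists held about the 605 genes that chance gives over both directions. The simulated overlaps are thus not matched in list size, and neither an excess nor a shortfall can be read from them. B3GNT6 lay at 1.76 and 1.58 and LAMA1 at 1.38 and 0.69 in the NOTCH1 and RBPJ knockdowns, while SDS lay at -0.28 and 1.28. With 2 control libraries the controls could not be split into parts of 2 libraries each. Part or all of the excess in correlation, covariance and shared sign may therefore come from the shared controls. Without replicate 1 of the RBPJ knockdown the correlation was 0.414 against a simulated 0.407, which left almost no excess.

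**Figure D3:**
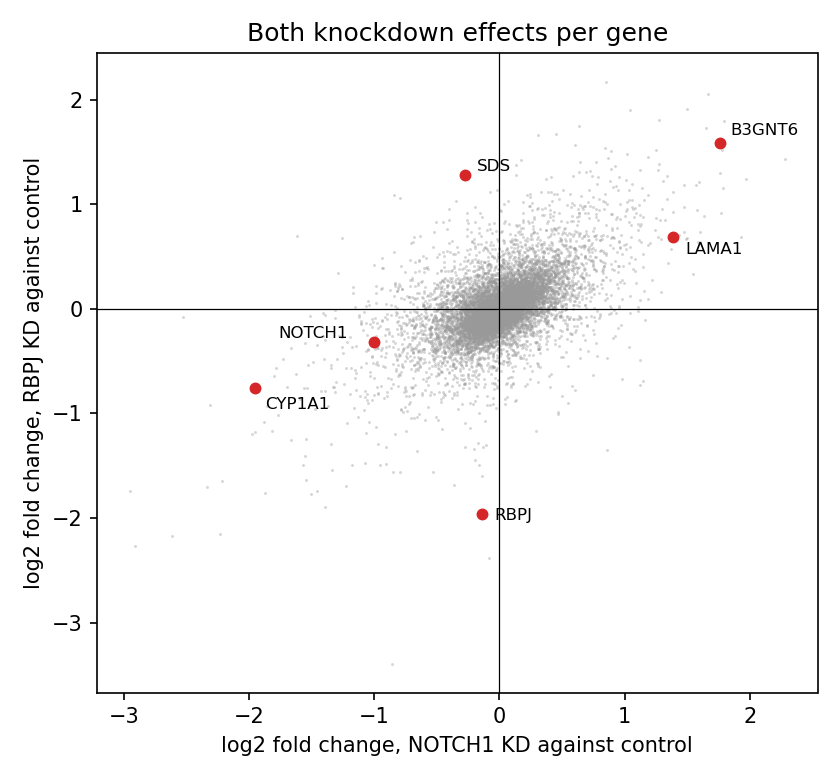
Log2 fold change against the control of each tested gene in the NOTCH1 knockdown (horizontal axis) and the RBPJ knockdown (vertical axis); each grey dot is a gene and 6 genes named in the text are red. B3GNT6 lies far from 0 in both (1.76 and 1.58), RBPJ in the RBPJ knockdown alone (-0.14 and -1.96). The correlation was 0.580, where unchanged groups simulated with equal spread in all groups gave 0.500 through the shared control libraries.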

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

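Combinations with the replicate block, and the block combined with an estimated correlation, were chosen after seeing the data. In none of the alternatives but the block did the NOTCH1 knockdown have more than 1 called gene: omitting a library gave 0 to 1. The RBPJ knockdown had 1 to 3 called genes and the direct comparison 0 to 3 when a library was omitted, and both had 0 without the variance trend, where RBPJ had a log2 fold change of -1.96 and an adjusted p of 0.332. The cause was not tested. Other pseudocounts, filters, scalings and thresholds left these 3 counts as they were. NOTCH1 in the NOTCH1 knockdown ran from -1.50 to -0.51 over omitted libraries and did not pass in any alternative.

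Replicate numbers are shared by the groups, and the series gives no shared day or collection behind them. Deviations of libraries with the same number from their group means correlated at 0.149 (control and NOTCH1 knockdown), 0.20 (control and RBPJ knockdown) and 0.213 (both knockdowns). All 3 lie above 0.1, but each comparison holds only 2 same-numbered pairs and the labels do not settle a pairing, so the numbers were read as names. This reading was settled with the counts already seen. A fit with the replicate block called 135 genes in the NOTCH1 knockdown (86 higher, 49 lower), 12 in the RBPJ knockdown (8 higher, 4 lower) and 15 in the direct comparison (4 higher, 11 lower), on 2 residual degrees of freedom. Combined with other settings these counts ran from 0 to 702, 0 to 378 and 0 to 184: without the trend all were 0, without a filter 2, and without replicate 2 of the control highest, on 1 residual degree of freedom. With the numbers swapped in the NOTCH1 knockdown, the block called 0, 1 and 1 genes in the 3 comparisons. With them swapped in the RBPJ knockdown it called 0, 1 and 2, and with both swapped 0, 1 and 0. The labelled numbers thus gave the most calls, which goes with libraries paired by number, although no shared collection is stated. With the labelled numbers the block gave 38 of the 188 single-gene results a call they lacked. It left 11 and 9 lists called against the control and raised the direct comparison's count of lists from 6 to 10, as did an adjusted p threshold of 0.10.

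With an estimated correlation, with fry, or with the block and an estimated correlation, 0 lists passed in all 3 comparisons. fry's test in either direction passed for hypoblast markers, with adjusted p values of 0.0196 in the NOTCH1 and 0.0113 in the RBPJ knockdown. With the block that test passed for 12 lists in the NOTCH1 and 2 in the RBPJ knockdown. Omitting a library left 8 to 12, 7 to 9 and 0 to 12 lists. Of 26 list calls, quantile normalization ended 3 and a minimum mean of 100 ended 2. The agreement of the knockdown effects was 0.609 with a minimum mean of 100 and ran from 0.414 to 0.728 over omitted libraries. Unchanged groups simulated with the same omissions, a simulation added after seeing the data, gave 0.666 to 0.668 without a control library, where 0.727 and 0.728 were observed, and 0.407 to 0.409 without a knockdown library, where 0.414 to 0.545 were observed, so most of the range follows from which group loses a library. Over all alternatives 3290 of 3346 single-gene values kept their sign and side of the threshold. Almost all of these results had no call to lose, since 0, 1 and 1 genes were called in the 3 comparisons. Of the 39 values that gained a call, 38 did so with the block.

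Signs turned within the range over omitted libraries in the RBPJ knockdown for NOTCH1 (-0.97 to 0.34, and 0.18 without replicate 2 of the control), MX1 (-0.34 to 1.63, and -0.17 without replicate 2 of the RBPJ knockdown), ZNF280A (-0.0127 to 0.40), DPPA2 (-0.0392 to 0.14), IFI27 (-0.54 to 4.34), DOT1L (-0.00725 to 0.43), COL1A1 (-0.0680 to 0.21) and COL1A2 (-0.22 to 0.0516). They turned in the NOTCH1 knockdown for KLF17 (-0.63 to 0.0889), ZSCAN4 (-0.42 to 0.0772), CD68 (-0.70 to 0.32), COL1A1 (-0.20 to 0.0707) and the mitotic list (-0.18 to 0.0401); none of these genes was called, and the cause was not tested. Spike-in scaling and the DESeq2 count test were not run, since no such rows or whole reads were used here. Scaling moved the median of all genes by less than the 0.1 that would need a correction. Low maternal transcripts rest on few reads.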

Other observations

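Of the tests below, those of omitted libraries and of fibroblast transcripts were chosen only after the result was seen. The values of 3 genes outside the fixed lists, chosen after they were seen, follow. None of the 3 passed without a replicate block. Calls with the block included COL18A1 in both knockdowns, GATA5 in the NOTCH1 knockdown and UCP2 in the RBPJ knockdown. COL18A1, a collagen of basement membranes, had 67.6 and 44.8 in the control, 180 and 132 in the NOTCH1 knockdown and 178 and 89.3 in the RBPJ knockdown, with log2 fold changes of 1.47 and 1.18 (limma, adjusted p = 0.357 and 0.983). UCP2, a mitochondrial carrier, had 94.1 and 78.4 in the control, 236 and 138 in the NOTCH1 knockdown and 208 and 152 in the RBPJ knockdown. GATA5, an endoderm transcription factor, had 31.7 and 57.8 in the control, 110 and 155 in the NOTCH1 knockdown and 80.7 and 56.5 in the RBPJ knockdown.

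Hypoblast markers were higher in both knockdowns as a list, a call lost with an estimated correlation (camera, adjusted p = 0.332 and 0.505). Replicate 1 minus replicate 2 in the list's median was -0.21 in the control, -0.097 in the NOTCH1 knockdown and 0.018 in the RBPJ knockdown. The control libraries thus differed by more than the NOTCH1 effect of 0.18. The higher hypoblast markers may be part of a wider shift of basement membrane genes. To test this on other genes, a list of 30 further basement membrane genes whose values had not been seen was written down. Of its 21 tested members, 15 were higher by sign in the NOTCH1 knockdown (median 0.21; camera, p = 0.0205) and 13 in the RBPJ knockdown (median 0.22; camera, p = 0.0179), with p = 0.0849 and p = 0.0808 with an estimated correlation. Scaling between libraries is argued against by quantile normalization, after which the hypoblast median was still 0.14 in the NOTCH1 knockdown, the lower of both. Cumulus, granulosa or fibroblast cells in the knockdown pools stay open. COL1A2, abundant in fibroblasts, had a log2 fold change of -0.25 in the NOTCH1 knockdown and -0.08 in the RBPJ knockdown, and COL1A1 had -0.07 and 0.07. The standard errors of 0.22 for COL1A2 and 0.16 for COL1A1 leave room for a small share of such cells, and both comparisons use the same controls.

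Maternal transcripts were lower in both knockdowns as a list, a call lost with an estimated correlation (camera, adjusted p = 0.486 and 0.505) and among genes with a mean of at least 100 (median -0.08 in both), and the source was not tested beyond the following. Scaling is argued against, since the median nearest 0 after quantile normalization was -0.51. A shift of the whole transcriptome along the axis on which replicates differ was examined only for the knockdown pairs. Outside the list, the RBPJ effect correlated at -0.0199 across 12072 genes with the difference between the NOTCH1 knockdown libraries. The NOTCH1 effect correlated at 0.0750 with that between the RBPJ knockdown libraries, where genes are not independent. Both correlations lay below the level set beforehand for such a shift, and the lower one was negative. Each axis rests on a single pair of libraries, where noise in single genes weakens a correlation, so a small shift along either axis is not excluded. The difference between the control libraries, which enters both effects, was not tested, so a shift along it stays open. Whether single libraries are the source is left open: in the NOTCH1 knockdown the call held without each library, with a median of at most -0.27, while in the RBPJ knockdown it was lost without replicate 2 of the control, at -0.18. Replicate 1 minus replicate 2 in the list's median was -0.30 in the control, -0.61 in the NOTCH1 knockdown and -0.12 in the RBPJ knockdown.

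CYP1A1 and CYP1B1, both induced by the aryl hydrocarbon receptor, had log2 fold changes of -1.95 and -1.86 in the NOTCH1 knockdown. In the RBPJ knockdown they had -0.76 and -0.93. None of these passed without a replicate block. With the block both genes passed in the NOTCH1 knockdown (limma, adjusted p = 0.00354 and 0.0217) and neither in the RBPJ knockdown (limma, adjusted p = 0.419 and 0.503). A lower output of the aryl hydrocarbon receptor's targets may be a candidate explanation. A list of other targets had a median of -0.0029 over 8 tested genes, 4 higher and 4 lower by sign, so the test does not decide.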
